A study of Rattus norvegicus with 9 samples.

How the data were processed

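Gene expression was measured by single-colour Affymetrix arrays in 9 samples of rat lung fibroblasts, 3 each from postnatal days 2, 7 and 21, each a pool of 5 pups (day 2) or 4 pups (days 7 and 21) of a litter numbered 1 to 3. Per the labels' protocols, cells were dispersed with trypsin and collagenase, adherent cells were kept after a short plating on plastic, total RNA was extracted with Trizol, and biotin-labelled cRNA was hybridised. The authors deposited probe set intensity values, made with RMA in the affy package per the submitters' processing notes. Versions, probe set definitions and any filter are not given in the sources used here. The deposited intensities are on a linear scale, whereas RMA itself returns log2 values, so log2 was taken before any test. RMA subtracts background, equalises the distributions of arrays and summarises probes, which compresses changes of dim probe sets and hides differences in total RNA between samples. The deposited arrays still differed, with medians of log2 5.24 to 5.66, so equal distributions cannot be assumed for these values. The tests had been fixed before the data were examined on the assumption that the file might be linear or log2, so the same tests were used.

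The file held 31099 probe sets on 9 arrays, no columns of other series and no arrays with identical values. The 57 AFFX control probe sets were left out of tests and used to describe RNA quality, and 31042 were tested. In the platform annotation used, 20826 probe sets had 1 gene symbol, 436 had several and 9780 had none here. Probe sets with several symbols were not named. Symbols were checked against a reference gene table through Entrez numbers, where 20758 were found and 0 changed. A gene with several probe sets was represented by the brightest over all arrays, which gave 14217 genes, and probe sets of a gene called in opposite directions occurred for 1, 29 and 12 genes in the comparisons of day 7 with day 2, day 21 with day 7 and day 21 with day 2. No genome was used, so no coordinates are given.

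Tests used limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with default settings), with a mean per day over all 9 arrays, no covariate, 6 residual and 5.69 prior degrees of freedom, two-sided tests and Benjamini-Hochberg adjustment within a comparison, calling probe sets at an adjusted p under 0.05. Profiles across days were intersections of the calls of the 2 intervals. The litters differ between the samples of a day, so the p-values measure spread between litters. Whether a litter number means the same litter on all days is not given in the sources used here. Dim probe sets were kept, and a level below log2 4.25, the 25th percentile of all values, is called the low end. The number of arrays, 3 per day, limits precision, and no detection calls were used here. Unless stated otherwise, errors are SEs from limma.

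For each comparison, the named genes were the 10 largest rises and the 10 largest falls among called genes whose arrays of the days compared did not overlap, leaving out uninformative symbols, and for the profiles the 10 genes with the largest smaller change. From each gene list up to 4 called members with the largest change could be named. All genes that changed steadily are named, and Rgs16 and Agtr2 among them, and genes named to show a value that was not called (Eln, Col1a1, Col3a1, Lamc1, Lama5), were singled out after their values were seen.

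The 44 gene lists were fixed before the data were examined, with 1375 members written and 1180 measured. They cover elastic fibre, interstitial collagen, basement membrane, matricellular, protease, myofibroblast, lipid-storing fibroblast, platelet-derived growth factor, TGF-beta and BMP, retinoid, Wnt, fibroblast growth factor, hedgehog, Notch, insulin-like growth factor, imprinted growth, angiogenic and guidance, Hox, mesenchymal transcription factor, proliferation, cell cycle inhibitor, glucocorticoid, antioxidant, oxidative phosphorylation, ribosomal, cholesterol, interferon, class II, inflammatory and early response genes, markers of general fibroblasts, macrophages, lymphocytes, granulocytes and mast cells, endothelium, alveolar type 2 and type 1 cells, airway, mesothelium, pericytes, erythroid cells, Schwann and neural cells and heart and skeletal muscle, and sex-linked genes. Some genes are in several lists. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over lists within a comparison. No camera call of any list held at an adjusted p under 0.05 when the correlation was estimated from the data. fry, which asks whether a list's genes move on balance in 1 direction without comparing them with other genes, was an alternative. Over-representation of lists in the profiles used Fisher's exact test, which treats genes as independent, adjusted over lists within a profile.

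The procedure was tested on simulated data over 31042 probe sets with 50 changed at each size. For day 7 against day 2, 2% of changes of 0.5 on the log2 scale, 80% of changes of 1 and 100% of changes of 2 or 3 were called in the right direction, with 10 unchanged probe sets called. For day 21 against day 7 the shares were 2%, 70% and 100%, with 9 unchanged probe sets called. The simulation drew independent noise and changed far fewer probe sets than were called in the data. Its shares therefore check the procedure and do not give the sensitivity or the false calls in these arrays.

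Of the alternatives, 22 were planned: leaving out each array, the litter number as a fixed or random block, only the arrays of the days compared, a variance trend with robust shrinkage, array weights, testing against a 1.2-fold change, a filter keeping the 17280 probe sets whose brightest day exceeds the median of log2 5.44, leaving out probe sets with names ending in _x_at or _s_at (30541 kept), a further quantile normalization, centring arrays on their medians, the mean of a gene's probe sets, camera with an estimated correlation, and fry. After seeing the data, 2 were added, the mean of the macrophage list as a covariate and leaving out day 2 replicate 1 and day 7 replicate 3 together.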

Results

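Gene expression was measured in lung fibroblasts freshly isolated from rat pups at 3 postnatal days that flank septation, the growth of ridges that divide the saccules of the newborn lung into alveoli. Day 2 lay before septation (the saccular stage), day 7 while it was under way, and day 21 after it had ended. Each of the 9 samples was a pool of cells from 5 pups (day 2) or 4 pups (days 7 and 21) of a single litter, with 3 litters per day, and each was hybridised to its own Affymetrix expression array. Cells were dispersed enzymatically and those that stuck to plastic after a short plating were kept. Other adherent lung cells could be among them, and macrophage markers were well expressed. The macrophage list averaged log2 6.97 to 9.56 per array, against medians of all probe sets of 5.24 to 5.66. The number of such cells was not measured. The median probe set intensity was 37.9 to 50.4 per array. The number of arrays, 3 per day, limits the precision of every value. Arrays of the same day correlated at 0.976 to 0.988 and arrays of different days at 0.881 to 0.974 across probe sets. Folds of genes whose lower level lay below log2 4.25, the low end of all values, are open to background, and so is their rank. The first principal component held 58.8% of the variance.

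The comparison of day 7 with day 2 asked which genes changed as septation got under way. Slit2, a secreted guidance cue, rose 3.26-fold to day 7 (log2 change 1.70 ± 0.26 SE, n = 3 arrays per day, limma adjusted p = 0.00336), and its change was 0.41 (adjusted p = 0.693) with the mean of the macrophage list as a covariate. The fibroblast growth factor receptors Fgfr4 and Fgfr3 rose by log2 1.43 ± 0.20 and 1.27 ± 0.24. Genes of macrophages, interferon response and inflammation fell, among them Fabp4, a lipid carrier of macrophages and fat cells (9.93-fold lower, log2 change -3.31 ± 0.33, adjusted p = 0.000516). Il1rn, the interleukin 1 receptor antagonist, was among them too (14.1-fold lower, log2 change -3.82 ± 0.43, adjusted p = 0.000815). The cartilage collagens Col2a1, Col9a1 and Col9a3 fell, Col9a1 and Col9a3 to below the low end, and the fetal growth gene Igf2 and its neighbour H19 also fell. In all, 1707 probe sets of 998 genes were higher at day 7 and 1068 probe sets of 627 genes were lower, together 8.94% of the 31042 tested. At least 2-fold were 414 of the rises and 522 of the falls.

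The 10 largest rises by the naming rule were those of Tril, Dnah7, Car3, Rprml, Lhfpl3, Pck1, Gstt3, Hsd11b2, Slit2 and Sytl2. Tril, an accessory protein of toll-like receptors, rose 4.56-fold (log2 change 2.19 ± 0.16, adjusted p = 8.63e-05). Car3, a cytosolic carbonic anhydrase, rose 3.72-fold and Hsd11b2, which inactivates glucocorticoids, rose 3.31-fold (log2 change 1.73 ± 0.18, adjusted p = 0.000523). Rprml rose 3.59-fold, Lhfpl3 3.47-fold, Gstt3, a glutathione transferase, 3.33-fold and Sytl2, a vesicle transport protein, 3.23-fold. Dnah7, an axonemal dynein (4.11-fold), and Pck1, the gluconeogenic carboxykinase (3.39-fold), also rose, from day 2 levels of log2 3.83 and 4.45, close to the low end of all values at 4.25.

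Of 28 measured genes of fibroblast growth factor signalling, 8 rose and 20 did not pass, with 8 rising adjusted over the list alone (camera adjusted p = 0.00142, adjusted p = 0.45 with an estimated correlation). Besides the receptors these included Fgf12 (log2 change 1.33) and the transcription factor Etv1 (1.27), a target of the pathway. Of 37 transcription factors of lung mesenchyme, 7 rose and 30 did not pass, with 12 rising and 1 falling adjusted over the list alone (camera adjusted p = 0.00594, adjusted p = 0.648 with an estimated correlation). Tbx5 (1.27), Nr2f1 (1.15) and Tbx4 (0.85) were the largest. Of 20 Hox genes and cofactors 3 rose, with 4 adjusted over the list alone (camera adjusted p = 0.0426, adjusted p = 0.648 with an estimated correlation). Hoxa5 (0.92), Hoxb3 (0.79) and Hoxb6 (0.69) were the 3 called. That list missed the threshold without day 2 replicate 3 (adjusted p = 0.143), day 7 replicate 1 (adjusted p = 0.0911) or day 7 replicate 2 (adjusted p = 0.101).

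Of 71 proliferation genes, 6 rose and 65 did not pass, with 13 rising adjusted over the list alone (median log2 change 0.32, camera adjusted p = 0.000605, adjusted p = 0.648 with an estimated correlation). The risers included Top2a (0.80 ± 0.15), a topoisomerase of dividing cells, Kif20a (0.80), Aurkb (0.78) and Tyms (0.72). Of 21 pericyte markers 4 rose, with 8 adjusted over the list alone (camera adjusted p = 0.0013, adjusted p = 0.333 with an estimated correlation). The guanylate cyclase subunits Gucy1a1 (1.27) and Gucy1b1 (1.17) and the growth factor receptor Pdgfrb (0.83) led them. Of 33 endothelial markers, 7 rose and 1 fell, with 10 and 1 adjusted over the list alone (camera adjusted p = 0.0221, adjusted p = 0.786 with an estimated correlation). Emcn (1.14), Tmem100 (1.07) and Cldn5 (0.87) were among the risers. The endothelial list missed the threshold without day 2 replicate 1 (adjusted p = 0.0962) or day 7 replicate 2 (adjusted p = 0.0888). Of 30 immediate early and heat shock genes, which respond to cell handling among other stimuli, 8 rose and 1 fell, with 9 and 2 adjusted over the list alone (camera adjusted p = 0.00816, adjusted p = 0.648 with an estimated correlation). Nr4a1 (1.08) and Fos (1.01) rose and Fosl1 (-1.33) fell. The 21 basement membrane genes shifted upward as a set (median 0.35, camera adjusted p = 0.0253, adjusted p = 0.786 with an estimated correlation). limma called none of them singly, with 6 higher at an unadjusted p under 0.05 and 5 higher adjusted over the list alone. Its set call was lost without day 2 replicate 1 (adjusted p = 0.0962), day 2 replicate 2 (adjusted p = 0.0579) or day 7 replicate 3 (adjusted p = 0.105). The values of Lamc1 and Lama5, its largest changes, were 0.73 and 0.71.

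The 10 largest falls were those of Col9a1, Stfa2l2, Col2a1, Stfa3, Col9a3, Spp1, Il1rn, S100a9, Fabp4 and S100a8. Col2a1, the main collagen of cartilage, fell 25.7-fold (log2 change -4.68 ± 0.52, adjusted p = 0.000743), Col9a1 34.1-fold and Col9a3 16.5-fold, the last pair to day 7 levels of log2 3.54 and 3.74 that lie below the low end and leave their folds open to background. Spp1, the secreted matrix protein osteopontin, fell 16.1-fold (log2 change -4.01 ± 0.61, adjusted p = 0.00312). The stefins Stfa2l2 and Stfa3, inhibitors of cathepsins, fell 31.2-fold and 17.7-fold, Stfa2l2 to a day 7 level of log2 4.17 that also lies below the low end. The neutrophil proteins S100a9 and S100a8 fell 14.1-fold and 8.08-fold.

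Of 35 measured macrophage markers, 20 fell and 15 did not pass, with 28 falling and 1 rising adjusted over the list alone (median log2 change -1.18, camera adjusted p = 1.06e-21, adjusted p = 0.333 with an estimated correlation). Fcgr2b, an Fc receptor (-3.01), Itgam, an integrin of myeloid cells (-2.55), and Ccr1, a chemokine receptor (-2.09), fell most after Fabp4. The mean log2 level of the list was 8.57 to 8.75 on the day 2 arrays and 6.97 to 7.76 on the day 7 arrays. Of 39 interferon response genes, 17 fell and 22 did not pass, with 22 falling and 2 rising adjusted over the list alone (median -0.69, camera adjusted p = 3.49e-13, adjusted p = 0.333 with an estimated correlation). Slfn4 (-2.44), Usp18 (-2.38), Oasl (-2.23) and Ifit3 (-2.19) fell most. With the mean of the macrophage list as a covariate the median change of the interferon list was -0.07 (median SE 0.38). Of 43 inflammatory genes, 19 fell and 24 did not pass, with 22 falling and 2 rising adjusted over the list alone (median -0.58, camera adjusted p = 2.85e-12, adjusted p = 0.333 with an estimated correlation). Besides Il1rn these were led by the chemokines Ccl9 (-3.01) and Cxcl3 (-2.72) and the siderophore binder Lcn2 (-2.46). With the covariate the median of the inflammatory list was -0.21 (median SE 0.44). Of 24 granulocyte and mast cell genes, 5 fell, also 5 adjusted over the list alone (camera adjusted p = 0.000326, adjusted p = 0.648 with an estimated correlation). S100a8, S100a9 and the antimicrobial peptides Camp (-2.73) and RatNP-3b (-2.49) were among them. Macrophage markers fell in the same comparison as each of these groups. Day 7 replicate 3 stood apart from day 7 replicates 1 and 2, with a mean log2 level of 6.97 against 7.68 and 7.76 for macrophage, 6.15 against 6.58 and 6.51 for interferon response and 7.27 against 7.74 and 7.68 for inflammatory genes, and the set calls of these 3 lists held without it.

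Of 38 antioxidant and detoxification genes, 9 fell and 2 rose, with 10 and 5 adjusted over the list alone. The quinone reductase gene Nqo1 (-2.54), Hmox1, which degrades haem (-2.14), and Gclc, of glutathione synthesis (-1.59), fell most. The list's median log2 change was 0.02 while its mean was -0.17 and its set test pointed down (camera adjusted p = 0.0381, adjusted p = 0.333 with an estimated correlation). The call was lost without day 2 replicate 3 (adjusted p = 0.0719), without day 7 replicate 1 (adjusted p = 0.0998) and after a further quantile normalization (adjusted p = 0.0593). Of 25 genes of lipid-storing fibroblasts, 6 fell and 2 rose, with 8 and 3 adjusted over the list alone (camera adjusted p = 0.0253, adjusted p = 0.45 with an estimated correlation). Its largest falls, Fabp4, Lpl (-1.89), Fabp5 (-1.40) and Cd36 (-1.13), are lipid uptake genes that macrophages also express. Of 17 imprinted genes of fetal growth, 3 fell, Igf2 (-2.51 ± 0.32, adjusted p = 0.00136), H19 (-2.07 ± 0.21, adjusted p = 0.000516) and Meg3 (-1.24 ± 0.29, adjusted p = 0.0202). With 4 falling and 2 rising adjusted over the list alone, the list did not pass as a set (camera adjusted p = 0.23), its median being 0.10, its mean -0.29 and its set test pointing down. Eln, the gene of elastin, was at log2 11.54 on day 2 and 11.83 on day 7 (adjusted p = 0.388). By limma there was no call for any gene of hedgehog signalling, oxidative phosphorylation, the ribosome, cholesterol synthesis or heart and skeletal muscle. Of these, in that order, 0, 7, 0, 3 and 0 were higher and 1, 0, 0, 0 and 1 lower at an unadjusted p under 0.05.

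**Figure D1:**
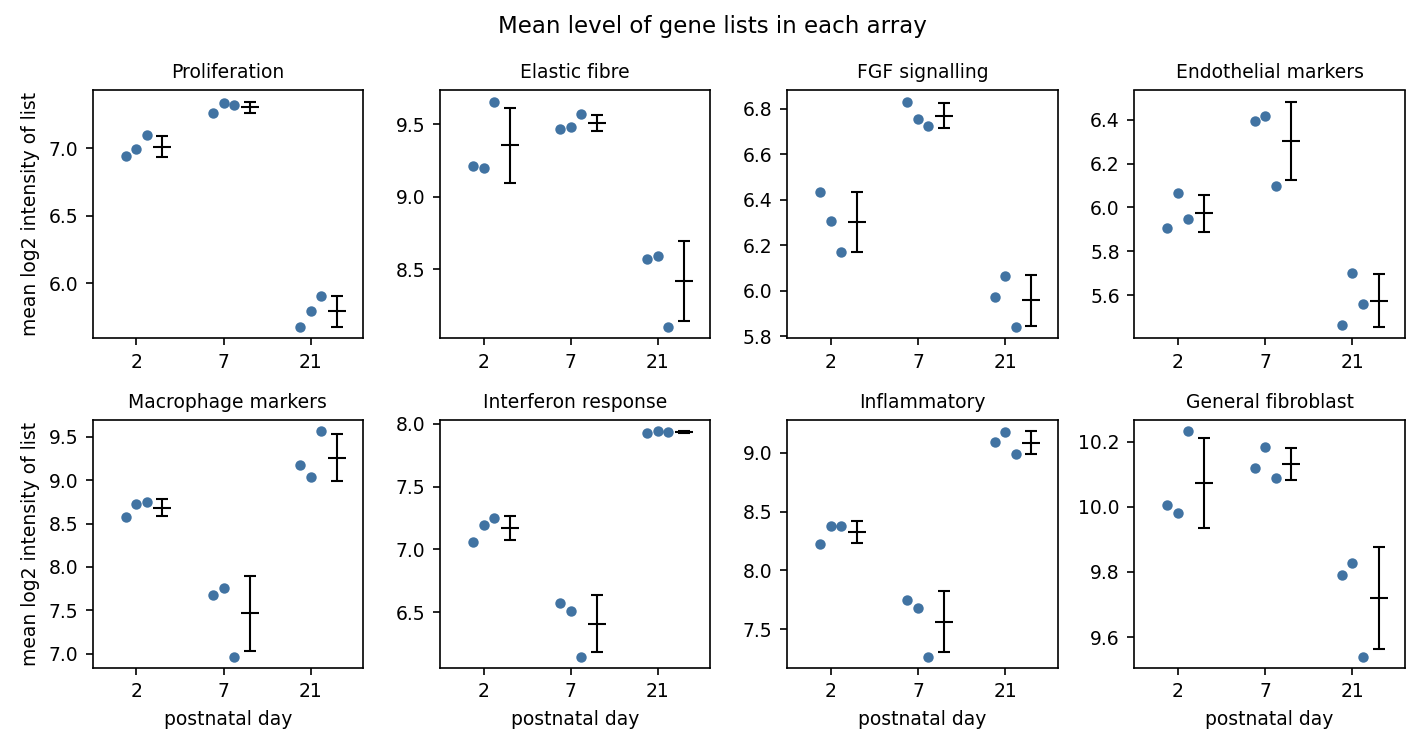
Mean log2 intensity of the measured members of 8 gene lists on each array (dots, n = 3 per postnatal day) with the mean and SD of each day (bar). The macrophage mean lay at 8.57 to 8.75 on day 2, 6.97 to 7.76 on day 7 and 9.04 to 9.56 on day 21.

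The number of calls between days 2 and 7 fell whichever array of those days was left out. Each omission also leaves fewer arrays for its day, so lost precision cannot be told apart from the weight of a single array. Without day 2 replicate 2, 850 probe sets were higher and 673 lower, and without day 2 replicate 3 the counts were 979 and 684. They were 1017 and 709 without day 7 replicate 2, and without day 7 replicate 1 893 were higher and 804 lower. Without day 2 replicate 1 the counts were 1307 and 751, and without day 7 replicate 3 they were 1185 and 734. The share of calls that were higher was 61.5% as deposited, 53.5% after a further quantile normalization and 41.5% with each array centred on its median, which left 902 probe sets higher. With the mean of the macrophage list as a covariate limma called 0 higher and 0 lower, with 2436 and 1543 at an unadjusted p under 0.05.

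The comparison of day 21 with day 7 asked what changed as septation ended, and it held the most calls. Genes of antigen presentation, macrophages and inflammation rose, with RT1-Db1, a class II histocompatibility chain, 20.2-fold higher at day 21 (log2 change 4.33 ± 0.30 SE, n = 3 arrays per day, limma adjusted p = 1.22e-06). The interferon-induced Ifit3 was 22.6-fold higher (4.50 ± 0.26, adjusted p = 4.54e-07). Proliferation genes fell, the mitotic kinase Cdk1 by 3.76 ± 0.21 on the log2 scale (adjusted p = 3.35e-07). So did genes that had been raised at day 7, with Slit2 38.7-fold lower (log2 change -5.27 ± 0.26, adjusted p = 1.9e-07) and Fgfr4 lower by log2 -4.25 ± 0.20. Most elastic fibre genes fell too, Fbn2, a fibrillin of developing tissue, by log2 -3.24 ± 0.21 (adjusted p = 8.54e-07). Eln itself was at log2 11.83 and 11.88 on days 7 and 21 (adjusted p = 0.861). In all, 3419 probe sets of 1954 genes were higher and 5920 of 3469 genes lower, 30.1% of those tested. At least 2-fold were 1503 and 2860 of them.

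Of the 10 largest rises, Serpinb2, a plasminogen activator inhibitor, was 35.7-fold higher at day 21 (log2 change 5.16 ± 0.35, adjusted p = 1.2e-06), from a day 7 level of log2 3.90. Col2a1 was 33.6-fold higher (5.07 ± 0.52, adjusted p = 2.04e-05). Cst7, a cathepsin inhibitor of immune cells, rose 26.9-fold, the channel gene Mcoln2 23.7-fold, the aldo-keto reductase Akr1b8 21.5-fold and Pkib 20.4-fold. The mast cell proteases Mcpt10 and Cpa3 rose 23.1-fold and 20.9-fold, Mcpt10 from a day 7 level of log2 3.00 and Mcoln2 from 3.67, both below the low end. On day 21 replicates 1, 2 and 3 Mcpt10 was uneven, at log2 6.42, 8.89 and 7.27, and so was Cpa3, at 8.04, 10.04 and 8.26. Col2a1 was also highest on day 21 replicate 2, at log2 10.84 against 9.09 and 8.39. The rest of the 10 are RT1-Db1 and Ifit3, above.

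Slc38a5, an amino acid transporter, had the largest fall by the naming rule, 67.2-fold (log2 change -6.07 ± 0.21, adjusted p = 3.97e-08), to a day 21 level of log2 4.13. Adamts19, a secreted metalloprotease, fell 41.6-fold, Rprml 36-fold, Unc79 36-fold and Col13a1, a transmembrane collagen, 35-fold (log2 change -5.13 ± 0.21, adjusted p = 8.01e-08). Enpep, an aminopeptidase that cleaves angiotensin, fell 30.1-fold, the diamine oxidase Aoc1 27.7-fold, Prom1 26.4-fold and the collagen Col25a1 21.1-fold. Slc38a5 ended below the low end, and so did Adamts19, Rprml, Unc79, Aoc1 and Col25a1 at log2 3.32 to 3.78, so their folds are open to background.

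Of 35 macrophage markers, 32 rose and 3 did not pass, with 34 adjusted over the list alone (median log2 change 1.86, camera adjusted p = 7.15e-17, adjusted p = 0.407 with an estimated correlation). Chi3l1 (2.87), Fcgr2b (2.79) and Cd37 (2.75) rose most. Their mean log2 level was 9.04 to 9.56 on the day 21 arrays. Of 39 interferon response genes, 31 rose and 1 fell, the same numbers adjusted over the list alone (camera adjusted p = 4.21e-15, adjusted p = 0.309 with an estimated correlation). Usp18 (3.56), Isg15 (3.47) and Cxcl11 (3.41) followed Ifit3. Of 43 inflammatory genes, 30 rose and 1 fell, with 33 and 2 adjusted over the list alone (camera adjusted p = 1.71e-14, adjusted p = 0.285 with an estimated correlation). Its largest rises were the chemokines Ccl22 (3.98), Ccl17 (3.84) and Ccl11 (3.71) and the cytokine Il6 (3.62). Of 13 class II antigen presentation genes, 10 rose and 3 did not pass, with 11 adjusted over the list alone (camera adjusted p = 6.97e-08, adjusted p = 0.36 with an estimated correlation). RT1-Ba (4.05), RT1-Bb (3.92) and the invariant chain Cd74 (3.30) came after RT1-Db1. Of 24 granulocyte and mast cell genes, 12 rose, with 13 adjusted over the list alone (camera adjusted p = 1.86e-06, adjusted p = 0.44 with an estimated correlation). After Mcpt10 and Cpa3 the largest was the chymase Cma1 (3.24). Of 28 lymphocyte genes 8 rose, also 8 adjusted over the list alone (camera adjusted p = 0.000847, adjusted p = 0.44 with an estimated correlation). Il7r (3.63), Cd4 (1.73), Cd2 (1.03) and Prf1 (0.88) rose most.

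Of 71 proliferation genes, 61 fell and 1 rose, with 63 and 1 adjusted over the list alone (median log2 change -1.40, camera adjusted p = 8e-20, adjusted p = 0.285 with an estimated correlation). Top2a (-3.32), Ccnb2 (-3.17) and the spindle kinase Ttk (-3.11) fell most after Cdk1. Of 20 elastic fibre genes, 14 fell, 4 rose and 2 did not pass, the same numbers adjusted over the list alone (median -1.31, camera adjusted p = 0.00527, adjusted p = 0.71 with an estimated correlation). Fbln5, which links elastin to cells (-3.36), Emilin1 (-2.50) and Mfap2 (-2.43) fell most beside Fbn2. With the mean of the macrophage list as a covariate the median change of the elastic fibre list was -0.36 (median SE 0.68). Of 55 genes of oxidative phosphorylation, 32 fell and 23 did not pass, with 34 adjusted over the list alone (median -0.56, camera adjusted p = 3.68e-05, adjusted p = 0.71 with an estimated correlation). Ndufs4 (-1.48) and Uqcrc2 (-1.23) fell most. Of 28 genes of fibroblast growth factor signalling, 12 fell and 2 rose, with 13 and 3 adjusted over the list alone (camera adjusted p = 0.0262, adjusted p = 0.562 with an estimated correlation). Fgfr3 (-3.83), Etv1 (-3.15) and Etv4 (-2.91) came after Fgfr4. The set call was lost with the mean of a gene's probe sets in place of the brightest (adjusted p = 0.0549). Of 33 endothelial markers, 18 fell and 4 rose, the same numbers adjusted over the list alone (camera adjusted p = 0.0168, adjusted p = 0.71 with an estimated correlation). Tmem100 (-3.48) and Emcn (-2.70) fell most, and the call was lost among brighter probe sets only (adjusted p = 0.0884). The pericyte list, with 12 of 21 markers falling and 2 rising, and 12 and 3 adjusted over the list alone, passed narrowly (camera adjusted p = 0.0448, adjusted p = 0.407 with an estimated correlation). Gucy1a1 (-2.62) and Gucy1b1 (-1.51) fell most. It missed the threshold without day 2 replicate 1 (adjusted p = 0.0508), day 7 replicate 2 (adjusted p = 0.0548) or day 21 replicate 3 (adjusted p = 0.102), after a further quantile normalization (adjusted p = 0.0517) and under 3 probe set choices (adjusted p of 0.0549 to 0.167).

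Of 38 antioxidant genes, 17 rose and 8 fell, with 17 and 9 adjusted over the list alone (camera adjusted p = 0.0248, adjusted p = 0.309 with an estimated correlation). Nqo1 (3.27) and Hmox1 (2.73) rose and Gsta4 (-3.19) and Cyp4b1 (-2.78) fell. The call was lost without day 7 replicate 1 (adjusted p = 0.0512). Of 30 early response genes, 12 rose and 2 fell, with 13 and 2 adjusted over the list alone (camera adjusted p = 0.0194, adjusted p = 0.562 with an estimated correlation). Fosl1 (2.34) and Junb (1.24) rose most. Of 25 lipid-storing fibroblast genes, 11 rose and 6 fell, with 12 and 6 adjusted over the list alone (camera adjusted p = 0.0356, adjusted p = 0.44 with an estimated correlation). Fabp4 (2.58), Lpl (1.96) and Fabp5 (1.95) rose and the transcription factor Tcf21 (-2.44) fell. Macrophage markers rose in the same comparison, and with the macrophage mean as a covariate the change of Fabp4 was -0.24 (adjusted p = 0.89). Fabp4 is itself in the macrophage list, so it was adjusted for a mean that contains it and part of this loss was built in. The call of the lipid-storing list was lost without day 21 replicate 3 (adjusted p = 0.0592), after a further quantile normalization (adjusted p = 0.0528) and with arrays centred (adjusted p = 0.0531). Of 26 markers of alveolar type 2 cells, 10 rose and 3 fell, with 10 and 4 adjusted over the list alone (camera adjusted p = 0.0356, adjusted p = 0.71 with an estimated correlation). Napsa (2.66), Epcam (1.37) and Krt8 (1.30) were the largest rises, and without day 7 replicate 3 the call was lost (adjusted p = 0.119).

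Other lists did not pass camera as sets between days 7 and 21. With fry, several of them were called downward, at adjusted p of 0.00304 to 0.0439. These were the angiogenic, mesenchymal transcription factor, imprinted, Hox, hedgehog, Wnt, insulin-like growth factor and retinoid lists. The interstitial collagen, basement membrane, general fibroblast, ribosomal, cholesterol and sex-linked lists were the others. fry called none of the rest. Of 22 contractile myofibroblast genes, 5 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.905), and the integrin gene Itga8 (-4.39) fell most. Of 27 interstitial collagen genes, 4 rose and 11 fell, with 4 and 13 adjusted over the list alone (camera adjusted p = 0.118). Col1a1 (log2 12.21 and 12.62, adjusted p = 0.28) and Col3a1 (log2 13.07 and 13.18, adjusted p = 0.625) were not called. Of 21 basement membrane genes, 2 rose and 9 fell, with 3 and 9 adjusted over the list alone, Nid1 (-2.43) and Lama5 (-2.36) the most (camera adjusted p = 0.261). Of 29 matricellular genes, 11 rose and 12 fell, also adjusted over the list alone, Spp1 (3.63) upward and Tnc (-2.77) downward. That list had a median of -0.17, a mean of -0.03 and a set test pointing up (camera adjusted p = 0.992). Of 32 proteases and inhibitors, 8 rose and 8 fell, with 9 and 9 adjusted over the list alone, Mmp13 (3.89) and Mmp3 (3.04) upward and Serpine2 (-2.57) downward. Its members had a median of -0.03, a mean of 0.03 and a set test pointing up (camera adjusted p = 0.677). Of 45 Wnt pathway genes, 3 rose and 16 fell, with 3 and 18 adjusted over the list alone, Wnt2 (-3.55) the most (camera adjusted p = 0.25). Of 11 hedgehog genes, 1 rose and 4 fell, also adjusted over the list alone, Gli2 (-2.15) and Gli1 (-1.96) the most. Hedgehog genes had a median of 0.24 but a mean of -0.29 and a set test pointing down (camera adjusted p = 0.812). Of 40 TGF-beta and BMP genes, 6 rose and 12 fell, with 8 and 14 adjusted over the list alone, Tgfb1 (2.71) upward and Bmp7 (-2.16) downward (camera adjusted p = 0.705).

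Of 25 retinoid genes, 1 rose and 6 fell, with 2 and 6 adjusted over the list alone, Adh1c (-3.85) and Crabp1 (-2.91) the most. Retinoid genes had a median of 0.10, a mean of -0.34 and a set test pointing down (camera adjusted p = 0.992). The 20 Notch genes split into 4 rising and 4 falling, also adjusted over the list alone (camera adjusted p = 0.677). The 6 platelet-derived growth factor genes split into 2 rising and 1 falling, also adjusted over the list alone, Pdgfra (-1.40) being the fall (camera adjusted p = 0.578). Of 40 angiogenic and guidance ligands and receptors, 7 rose and 16 fell, with 7 and 18 adjusted over the list alone, Vegfd (-3.86) and Mdk (-3.70) after Slit2 (camera adjusted p = 0.0665). Of 37 mesenchymal transcription factors, 3 rose and 17 fell, with 4 and 17 adjusted over the list alone, Meox2 (-4.08) the most (camera adjusted p = 0.056). Of 17 imprinted growth genes, 2 rose and 10 fell, also adjusted over the list alone (median -0.65, camera adjusted p = 0.0918). Among 20 Hox genes and cofactors 1 rose and 7 fell, with 1 and 8 adjusted over the list alone, a median of -0.0074 and a mean of -0.43 (camera adjusted p = 0.229). Of 18 insulin-like growth factor genes, 2 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.425). Of 19 cell cycle inhibitors 5 rose and 5 fell, with 6 and 6 adjusted over the list alone (median -0.05, mean -0.0037, set test pointing up, camera adjusted p = 0.677). Of 22 glucocorticoid response genes 8 rose and 3 fell, with 10 and 4 adjusted over the list alone, Hsd11b1 (-3.32) the largest (camera adjusted p = 0.0641). Of 19 cholesterol synthesis genes, 2 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.189). Of 34 ribosomal protein genes 1 fell, Rpl28 (-0.73), also 1 adjusted over the list alone (camera adjusted p = 0.533).

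Among markers of cell types, the 23 general fibroblast markers split into 5 rising and 10 falling, also adjusted over the list alone. They had a median of 0.003, a mean of -0.41 and a set test pointing down (camera adjusted p = 0.578). Of 15 type 1 alveolar cell markers, 3 rose and 5 fell, with 5 and 5 adjusted over the list alone (camera adjusted p = 0.677). Of 24 airway markers 3 rose and 3 fell, also adjusted over the list alone, the club cell gene Scgb1a1 (3.16) the largest rise (camera adjusted p = 0.154). Of 13 mesothelial markers 3 rose and 1 fell, with 5 and 1 adjusted over the list alone, Msln (2.53) the most (camera adjusted p = 0.109). Erythroid (2 of 24 up, 5 down, also adjusted over the list alone, camera adjusted p = 0.94), Schwann and neural (3 of 19 up, 2 down, also adjusted over the list alone, camera adjusted p = 0.523) and heart and skeletal muscle markers (3 of 24 up, 2 down, with 2 and 2 adjusted over the list alone, camera adjusted p = 0.106) did not pass. Of 5 sex-linked genes Rps4y2 (-1.75) fell, also adjusted over the list alone (camera adjusted p = 0.425).

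Of the 3 control genes that compare the 3′ with the 5′ end of a transcript as a sign of RNA quality, hexokinase was higher on day 21, with log2 ratios of 1.07 to 1.33 against 0.56 to 0.91 on day 7 and 0.37 to 0.87 on day 2. The beta-actin ratio was 0.49 to 0.73 on day 21 against 0.71 to 1.18 on day 7, and the GAPDH ratio 0.11 to 0.24 against -0.11 to 0.25. The falls in proliferation, elastic fibre and oxidative phosphorylation genes and the rises in immune genes belong to the same comparison. The share of calls that were higher at day 21 was 36.6% as deposited, 48.5% after a further quantile normalization and 48% with each array centred on its median. Centring moved the median change of all probe sets from 0.02 to 0.13. With the mean of the macrophage list as a covariate limma called 4 probe sets higher and 21 lower, and the calls of Ifit3 (2.58, adjusted p = 0.129), RT1-Db1 (3.20, adjusted p = 0.213) and Slit2 (-3.36, adjusted p = 0.0866) were lost.

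**Figure D2:**
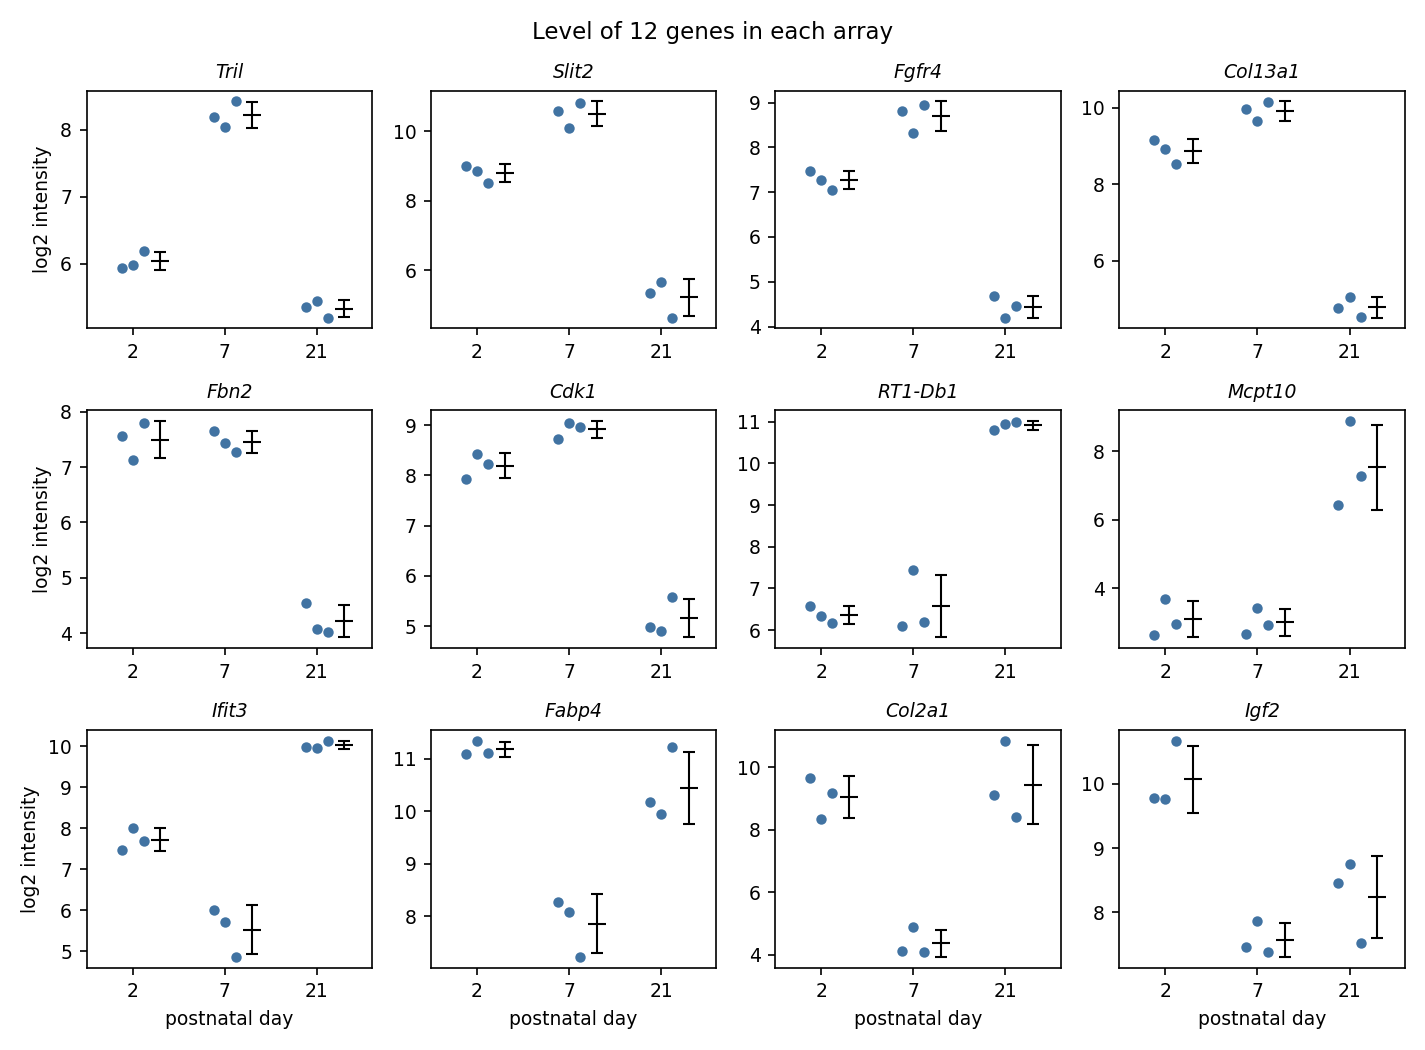
Log2 intensity of 12 genes on each array (dots, n = 3 per postnatal day) with the mean and SD of each day (bar). Slit2 averaged 8.79, 10.50 and 5.22 on days 2, 7 and 21, whereas Col2a1 averaged 9.06, 4.37 and 9.44.

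Day 21 against day 2 gave the net change across septation. Class II antigen presentation genes and mast cell proteases were among the largest rises, RT1-Db1 23.4-fold (log2 change 4.55 ± 0.30 SE, n = 3 arrays per day, limma adjusted p = 3.38e-06). RT1-Ba rose 19.7-fold, RT1-Bb 19.1-fold, Cd74 9.84-fold, Mcpt10 21.6-fold from log2 3.09 and Cpa3 14.8-fold. The chemokines Ccl11, Ccl22 and Ccl17 rose 19-fold, 12.5-fold and 11.9-fold and Fam180a 15.2-fold. Adamts19 fell 27.6-fold (log2 change -4.79 ± 0.20, adjusted p = 3.7e-07), Slc38a5 27.5-fold, Aoc1 25.8-fold and Stfa3 21.1-fold. Col13a1 fell 16.9-fold, Enpep 16.7-fold, Unc79 16.3-fold, the endopeptidase Mme 13.1-fold, Srpx2 12.9-fold and Col25a1 12.1-fold. Adamts19, Slc38a5, Aoc1, Stfa3, Unc79 and Col25a1 ended at log2 3.32 to 4.20, below the low end. In all, 2118 probe sets of 1251 genes were higher and 3773 of 2176 genes lower, 19% of those tested, with 702 and 1444 of them at least 2-fold.

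Of 71 proliferation genes, 57 fell and 14 did not pass, with 59 falling and 1 rising adjusted over the list alone (median -1.14, camera adjusted p = 1.27e-25, adjusted p = 0.237 with an estimated correlation). Cdk1 (-3.03), Ttk (-2.65) and Ccnb2 (-2.61) fell most. Of 20 elastic fibre genes, 11 fell and 2 rose, with 12 and 3 adjusted over the list alone (camera adjusted p = 0.000754, adjusted p = 0.78 with an estimated correlation). Fbn2 (-3.28), Fbln5 (-2.56) and Mfap2 (-2.30) fell most. Of 17 imprinted growth genes, 10 fell and 2 rose, with 10 and 3 adjusted over the list alone (median -1.14, camera adjusted p = 0.00109, adjusted p = 0.569 with an estimated correlation). H19 (-2.72), Mest (-2.68) and Meg3 (-2.29) fell most. Of 55 oxidative phosphorylation genes 15 fell, with 18 adjusted over the list alone (camera adjusted p = 0.000136, adjusted p = 0.78 with an estimated correlation), beside the same control ratios. Of 27 interstitial collagen genes, 8 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.0489, adjusted p = 0.78 with an estimated correlation). Col13a1 and Col16a1 (-1.48) fell and Col15a1 (1.44) rose. The collagen call was lost without day 2 replicate 3 (adjusted p = 0.275), day 7 replicate 3 (adjusted p = 0.0562) or day 21 replicate 3 (adjusted p = 0.173), and under 3 probe set choices (adjusted p of 0.0561 to 0.165).

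Of 39 interferon response genes, 26 rose and 1 fell, with 30 and 1 adjusted over the list alone (camera adjusted p = 2.44e-10, adjusted p = 0.5 with an estimated correlation). Of 43 inflammatory genes 18 rose and 3 fell, with 25 and 3 adjusted over the list alone (camera adjusted p = 1.39e-07, adjusted p = 0.5 with an estimated correlation). Saa3 (-2.67) was the largest fall. Of 30 early response genes 15 rose, with 17 adjusted over the list alone (camera adjusted p = 2.55e-08, adjusted p = 0.307 with an estimated correlation). Junb (1.54) and Nr4a3 (1.36) rose most. Of 13 class II genes 9 rose, also adjusted over the list alone (camera adjusted p = 1.47e-06, adjusted p = 0.5 with an estimated correlation). Of 35 macrophage markers 11 rose and 24 did not pass, with 12 adjusted over the list alone (median 0.52, camera adjusted p = 8.16e-05, adjusted p = 0.78 with an estimated correlation). Of 28 lymphocyte genes 9 rose, also adjusted over the list alone (camera adjusted p = 0.000146, adjusted p = 0.546 with an estimated correlation). Of 24 granulocyte and mast cell genes, 12 rose and 4 fell, with 13 and 6 adjusted over the list alone (camera adjusted p = 0.013, adjusted p = 0.78 with an estimated correlation). The mast cell chymase Cma1 (3.05) rose and the neutrophil S100a9 (-2.87) fell, in a call lost without day 2 replicate 1 (adjusted p = 0.0665). Of 26 type 2 alveolar markers 3 rose, also adjusted over the list alone (camera adjusted p = 0.0475, adjusted p = 0.78 with an estimated correlation). These were Napsa (1.86), Sftpa1 (1.22) and Dram1 (0.65), in a call lost without day 2 replicate 3 (adjusted p = 0.119), without day 21 replicate 2 (adjusted p = 0.0672) and after a further quantile normalization (adjusted p = 0.0522). Without day 2 replicate 2, 1186 probe sets were higher at day 21 than at day 2. The share of calls that were higher was 36% as deposited, 47.3% after a further quantile normalization and 39.6% with arrays centred. With the macrophage covariate 577 probe sets were higher and 1260 lower.

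The profiles across all 3 days asked which genes were specific to the day of active septation. Most of what rose to day 7 fell again: 1490 probe sets of 869 genes were highest at day 7, which is 87.3% of the rises, and 847 of 535 genes were lowest there, 79.3% of the falls. The genes highest at day 7 had median log2 changes of 0.79 to day 7, -1.38 from day 7 to day 21 and -0.57 from day 2 to day 21. A typical gene of that set thus ended below its day 2 level. For the genes lowest at day 7 these medians were -1.09, 1.61 and 0.43. Tmem178a, a membrane protein (1.63 ± 0.22 up, then -3.03 ± 0.22), completed the 10 genes highest at day 7 by the naming rule with Tril, Dnah7, Car3, Rprml, Lhfpl3, Pck1, Gstt3, Hsd11b2 and Slit2. The 10 lowest were Col2a1, Col9a1, Spp1, Il1rn, Col9a3, Ccl9, Il7r, Fcgr2b, Cxcl3 and Fabp4, and Il7r, a cytokine receptor, fell by 2.95 ± 0.20 on the log2 scale and then rose by 3.63 ± 0.20.

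Genes lowest at day 7 held 20 of 35 macrophage markers (two-sided Fisher's exact test over 14217 genes, adjusted p = 1.93e-18), 17 of 39 interferon response genes (adjusted p = 2.47e-13), 17 of 43 inflammatory genes (adjusted p = 1.18e-12), 8 of 38 antioxidant genes (adjusted p = 0.000757), 5 of 25 lipid-storing fibroblast genes (adjusted p = 0.0185) and 5 of 32 proteases (adjusted p = 0.0471). Fisher's test treats genes as independent, whereas the macrophage markers varied together within days (mean pairwise correlation 0.528) and some genes are in several lists. These p-values therefore overstate the evidence. Genes highest at day 7 held 7 of 28 fibroblast growth factor genes (adjusted p = 0.0522) and 7 of 33 endothelial markers (adjusted p = 0.0721), and no list passed. The retinoid receptor Rxrg was among them, at log2 4.95, 6.44 and 4.91 on days 2, 7 and 21.

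Steady change was rare. Genes rising in both intervals numbered 11 (20 probe sets): Angpt2, Bex1, Cd83, Cyp2j3, Ecm2, Mamdc2, Pcsk5, Pdgfrl, Rgs16, Tbc1d4 and Tst, of which Rgs16, a regulator of G protein signalling, rose by 1.30 ± 0.19 and 0.87 ± 0.19. Genes falling in both numbered 11 (18 probe sets): Adora2b, Agtr2, Bhlhe22, Capn6, H19, Igf2bp2, Meg3, Nrk, Pcdh20, Plag1 and Sncaip, of which the angiotensin receptor Agtr2 fell by 1.51 ± 0.18 and 1.83 ± 0.18. Independent lists of these sizes would share 188 rising and 204 falling probe sets. The shared day 7 arrays make the changes of the 2 intervals oppose each other, so part of this shortfall was built in. Without day 7 replicate 1, 7 probe sets rose and 10 fell in both intervals, so which genes are named depends on the arrays kept.

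**Figure D3:**
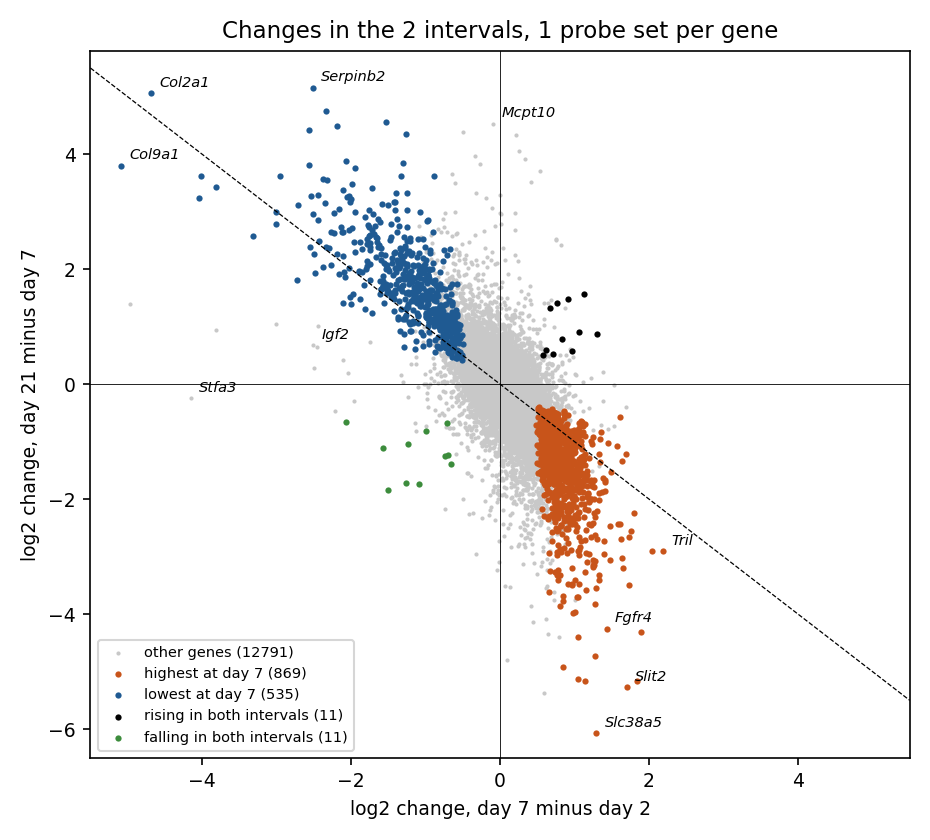
Log2 change from day 2 to day 7 (horizontal axis) against log2 change from day 7 to day 21 (vertical axis), 1 dot per gene, with genes coloured by profile and a dashed line where a change is fully undone. The 869 genes highest and 535 genes lowest at day 7 lie at the lower right and upper left, and 11 genes rose and 11 fell in both intervals.

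Both intervals share the day 7 arrays, which alone makes their changes oppose each other. In 20 simulations of unchanged genes the correlation of the 2 changes averaged -0.50 against the observed -0.66 across genes, which are not independent replicates, and the covariance -0.02 against -0.21, so that -0.19 lay beyond the shared arrays. The simulations gave 0 probe sets highest and on average 0.05 lowest at day 7, and independent lists would share 326 and 118, but part of the excess may come from the shared arrays. Probe sets highest at day 7 numbered 762 without day 2 replicate 2, 872 without day 2 replicate 3, 806 without day 7 replicate 1, 931 without day 7 replicate 2 and 986 without day 7 replicate 3, and 787 with arrays centred. Those lowest numbered 558 without day 2 replicate 2 and 546 without day 2 replicate 3.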

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

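Most named changes kept their direction and call, while the number of calls, above all between days 2 and 7, depended on the arrays kept and on settings. The macrophage covariate and the joint omission of 2 arrays were chosen only after the results were seen, and all other alternatives were fixed before the data were examined. When each array was left out in turn, probe sets higher at day 7 than at day 2 ranged from 850 to 1814 and those lower from 673 to 1155. Probe sets higher at day 21 than at day 2 ranged from 1186 to 2565. Those highest at day 7 ranged from 762 to 1520, lowest at day 7 from 546 to 903, rising in both intervals from 7 to 23 and falling in both from 10 to 17. Leaving out day 2 replicate 1 and day 7 replicate 3 together gave 612 lower at day 7 than at day 2, 962 highest, 524 lowest, 13 rising and 10 falling. No called probe set was called in the opposite direction under the alternatives run for all probe sets, although the values of 3 named genes turned, without a call, under the macrophage covariate.

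Scaling moved some counts. Centring each array on its median gave 902 probe sets higher at day 7 than at day 2 and 787 highest at day 7. A further quantile normalization gave 3397 higher at day 21 than at day 2 and 33 rising in both intervals. Array weights gave 2982 higher at day 7 than at day 2, 2281 highest at day 7, 50 rising and 33 falling. Testing against a 1.2-fold change gave 484 higher and 459 lower at day 7 than at day 2. The same test gave 2043 higher at day 21 than at day 7, and 838 higher and 1896 lower at day 21 than at day 2. It left 434 highest, 389 lowest, 3 rising and 7 falling.

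With the mean of the macrophage list as a covariate, limma called 0 probe sets higher and 0 lower at day 7 than at day 2, with 2436 and 1543 at an unadjusted p under 0.05. It called 4 higher and 21 lower at day 21 than at day 7, and 577 higher and 1260 lower at day 21 than at day 2. No probe set was then highest (0), lowest (0), rising (0) or falling (0) across the days. The covariate differs between days far more than within them, so the fit has little left to estimate either, and the median SE of the genes highest at day 7 rose from 0.17 to 0.36. Median changes of lists under it were, for interferon response, -0.07 (-0.69 without it) to day 7 and 0.75 (1.24) from day 7 to day 21, and for inflammatory genes -0.21 (-0.58) and 0.96 (1.43). Elastic fibre genes went from -1.31 to -0.36 (median SE 0.68) from day 7 to day 21, endothelial markers from -0.79 to -1.15 and proliferation genes from -1.40 to -1.48 (median SE 0.52). Under it 26 of the changes of named genes kept their call and 53 lost it, 39 with a smaller and 14 with a larger value than before. Another 3 reversed, all from day 7 to day 21: Il1rn to -0.55 (adjusted p = 0.729), Fcgr2b to -0.26 (adjusted p = 0.913) and Fabp4 to -0.24 (adjusted p = 0.89). Fcgr2b and Fabp4, unlike Il1rn, are in the macrophage list, so they were adjusted for a mean that contains them.

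Gene lists were the results that depended most on the test. With an estimated correlation camera called 0 lists in each of the comparisons, day 7 with day 2 (0), day 21 with day 7 (0) and day 21 with day 2 (0). fry called 10, 29 and 15, and 11 camera calls were lost with it. Among the lost calls were the granulocyte and mast cell list for day 7 against day 2 (fry adjusted p = 0.189) and the macrophage list for day 21 against day 2 (fry adjusted p = 0.0867). Among brighter probe sets only, the call of the endothelial list between days 2 and 7 was also lost (adjusted p = 0.0766). With day 2 replicate 1 and day 7 replicate 3 out together, the proliferation (adjusted p = 0.0985), mesenchymal transcription factor (adjusted p = 0.0617), early response (adjusted p = 0.0845) and basement membrane (adjusted p = 0.305) lists lost theirs there. List tests were not run with array weights, the variance trend, the 1.2-fold test or the covariate. The cause of these losses was not tested.

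Samples of different days share a litter number from 1 to 3, and the labels do not say whether it marks the same litter. After removing day means, arrays with the same number correlated at -0.24 to 0.41, with 2 of 9 pairs over 0.1, both between days 2 and 7 (0.41 and 0.22, the other pair 0.08). All 3 day 7 arrays correlated better with the day 2 array of their own number than with the other day 2 arrays, against 1 of 3 pairs of days 21 and 2 and 0 of 3 of days 21 and 7. As not every pair of any comparison passed 0.1, the samples were treated as sharing only a number, and the match of days 2 and 7 is a hint from the data. The GAPDH control ratio rose with that number on both days (-0.07, 0.02 and 0.16 on day 2, -0.11, -0.05 and 0.25 on day 7). So did the hexokinase ratio, whereas the beta-actin ratio did not. RNA quality or handling that follows the number therefore cannot be told apart from a shared litter. With the litter number as a fixed replicate block, the counts were 1504 higher and 999 lower at day 7 than at day 2, 3375 and 5904 at day 21 against day 7, and 2017 and 3800 at day 21 against day 2. As a random replicate block they were 1605 and 1007, 3328 and 5821, and 1997 and 3641, with a consensus correlation of -0.0288. No count of called probe sets in a comparison moved by more than 1.5 times. With the fixed replicate block the calls of the antioxidant list for day 7 against day 2 (adjusted p = 0.0569) and of interstitial collagens for day 21 against day 2 (adjusted p = 0.0519) were lost. With the random replicate block the Hox (adjusted p = 0.0658) and basement membrane lists (adjusted p = 0.0568) lost theirs for day 7 against day 2. So did the lipid-storing fibroblast (adjusted p = 0.0768), pericyte (adjusted p = 0.0768) and alveolar type 2 lists (adjusted p = 0.0525) for day 21 against day 7, and the alveolar type 2 list for day 21 against day 2 (adjusted p = 0.0674).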

Other observations

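Some biology lies outside the comparisons. The Y-linked Eif2s3y was at log2 3.68 on day 2 replicate 1, against 7.99 and 7.07 on the other day 2 arrays and 5.94 to 7.88 on the arrays of days 7 and 21, and the X-inactivation transcript Xist was at 11.28 there and 9.10 to 10.57 on the others. The probe sets named Uty and Rps4y2 were not low on that array, at log2 8.62 and 7.59. Sex is not given per array in the sources used here.

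The first pattern is the dip of macrophage genes at day 7, and both tests of it were chosen only after the result was seen. If macrophages were fewer in the day 7 preparations, their genes were predicted to vary together within days, and they did. Their mean pairwise correlation within days was 0.528, where the highest of 1000 random lists reached 0.1314. Without the arrays of day 2, 7 or 21 it was 0.62, 0.41 and 0.52 against 0.22, 0.17 and 0.11. Day means were removed first and the random lists were matched only on level, so this cannot show that day 7 differed from the other days. Against a smaller share of fibroblasts with all other cells alike counts that endothelial markers changed by log2 1.53 more than macrophage markers (SDs 0.44 and 0.83). Co-variation could equally come from a shared change of activity within macrophages, which these arrays cannot separate from their number. A real difference in resident macrophages between the stages stays open as well, untested here.

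The second pattern is the dip of cartilage genes at day 7, where the brighter genes and the covariate values were tests chosen only after the result was seen. If cartilage cells had been carried into the day 2 and day 21 preparations, other cartilage genes should follow, and 2 of 13 did (15.4%, exact 95% interval 1.92 to 45.4), under the bound of 50% set beforehand. That bound was too strict, because 6 of the 13 were dim on days 2 and 21 and 10 had a lower mean at day 7 than on both other days, and among the 7 brighter genes 1 followed (interval 0.361 to 57.9%), so carry-over stays open. So does carry-over in amounts that differ between arrays. Within days the 13 genes correlated with the first 5 at a mean of 0.5428, above the 95th percentile of random lists (0.3507). Of 1000 random lists 1 was as high (0.5492), and the prediction had asked for none. Correlations of the 13 genes ran from 0.97 (Col11a1) to -0.09 (Chadl), with 6 over 0.7. As to a change like that of macrophages, the median of 18 cartilage genes fell by 0.51 less (bootstrap SD 0.54). Dim genes are among them, so the medians cannot decide. With the macrophage mean as a covariate Col2a1 went from -4.68 ± 0.52 to -5.70 ± 1.19. Col9a1 went from -5.09 ± 0.60 to -6.40 ± 1.35 and Col9a3 from -4.05 ± 0.51 to -5.08 ± 1.17. None was smaller, but none was still called as the errors grew. Falls of Col9a2 (to -3.45 ± 1.11), Cnmd (-4.10 ± 1.19), Comp (-2.88 ± 1.04) and Col11a1 (-2.92 ± 1.01) also grew. A dip following the macrophage mean should have shrunk, and none of these did. These are, however, the cartilage genes that the same arrays called lowest at day 7, and they vary together, so they are not separate evidence. The covariate left the fit little to estimate, and some day 7 levels lay below the low end. The covariate values therefore cannot decide. A change with age in the fibroblasts is untested.

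The third pattern is the peak of genes at day 7, and both tests of what makes it were chosen only after the result was seen. As to a larger share of fibroblast RNA at day 7, the genes highest at day 7 fell to day 21 by log2 1.39 more than the general fibroblast list (SD over its members 1.38, a narrow margin) and rose by 0.79 more (SD 0.40). Those genes had been picked from these arrays for such a rise and fall, so larger medians were built in and the comparison cannot decide. The general fibroblast list itself had a median change of 0.0088 to day 7, with 0 of 23 members called higher and 1 lower. Proliferating cells stay open, since 6 of 71 proliferation genes (8.45%) and 6.1% of other genes were highest at day 7 (odds ratio 1.42, 95% interval 0.502 to 3.28). With the macrophage mean as a covariate the median rise of these genes was 0.64 (median SE 0.36) and that of the genes lowest at day 7 -0.57 (SE 0.38), so how far either follows the cell mixture stays open. Stage of septation, age and preparation change together across the days and could not be separated.

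Regrouping the arrays tested chance, with tests chosen before the results were seen. Splitting the 6 arrays of a comparison into 3 and 3 can be done in 10 ways, too few for a share under 0.05. The real split was the only 1 of 10 with as many calls for day 7 against day 2 (2775, highest other 0), and likewise 1 of 10 for day 21 against day 7 (9339, highest other 0) and 1 of 10 for day 21 against day 2 (5891, highest other 0). Of 100 groupings of all arrays, 2 gave as many probe sets highest in the middle group (real 1490, highest other 1540), 3 as many lowest (real 847, highest other 3221), 1 as many rising (real 20, highest other 5) and 1 as many falling (real 18, highest other 2). The others as large follow the structure of the samples: both had the 3 day 21 arrays in the middle, with days 2 and 7 intact on either side (1540 and 3221) or mixed (1065 and 2597). The 96 groupings with a mixed or day 2 middle gave 0 at most. Most groupings mix days, which puts the differences between days into the spread and lowers their calls. These shares therefore show that the 3 days differ, and cannot tell whether chance made the profiles at day 7.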
